A study of Arabidopsis thaliana with 6 samples.

How the data were processed

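RNA was sequenced from wild-type Arabidopsis thaliana grown for 7 days on plates of MS medium, a mineral medium for plant culture, and then kept for 12 h with 0, 100 or 1000 µM melatonin. Per the labels' protocols, total RNA was taken from rosette leaves with Qiagen's RNeasy mini kit, its integrity was examined on a Bioanalyzer, and libraries followed Illumina's standard protocols. Whether poly(A) RNA was selected and whether the libraries keep the strand are not given in the sources used here. Samples were put into groups by the treatment given in the labels, which makes 3 groups of 2 libraries. Nothing in the labels says whether the 2 libraries of a group came from separate plants or plates, and no batch or date is given.

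The deposited table holds whole-number read counts per gene, with no normalisation by the authors visible in the values: the 6 columns add up to different totals. Per the submitters' processing notes, Bowtie2 2.2.3, TopHat2 2.0.12, HTSeq 0.6.1 and DESeq 1.18.0 were used with the genome build TAIR10. The role and order of these tools, their options and the strand setting of the counting are not given in the sources used here. Counting without strand cannot separate overlapping genes, and reads shared by near-identical genes may be dropped or split. Of the 134 genes named by the rule below, 32 overlap another gene of the table, so that their values are less certain: IAA3, TSO2, CHLD, ARR6, ASN1, XTH15, CYP81D11, GSTU7, HSP101, MBF1C, BHLH101, LHCB3, FRK1, PAT1, AT4G25090, CHLM, GR1, PORC, PORB, BOA, BCAT4, RCA, LHCB6, PYK10, EXPA7, SKOR, ABCB4, CYCD3;1, KNOLLE, CDKB2;1, CHLI1 and UGT73B4.

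The table has 32678 genes, and library totals were 6784239 and 7333967 counts in the controls, 6641570 and 6410046 at 100 µM, and 7651170 and 7723602 at 1000 µM. Gene symbols and product names were taken from a RefSeq table of the assembly TAIR10.1, in which 31912 of the 32678 identifiers were found and 766 were not. Its assembly differs from the authors' build, so it served for names and for which genes overlap, and no coordinates are given.

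Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr, which left 18380 genes to test and took out 14298, and libraries were scaled with TMM. Every change in a gene was tested with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, two-sided) on all 6 libraries with the 3 groups as the only term, and adjusted over all tested genes by Benjamini-Hochberg with a threshold of 0.05. The groups thereby share one estimate of the spread, with 3 residual degrees of freedom and 14.1 prior degrees of freedom. The biological coefficient of variation was 7.8%. Log2 fold changes are given ± a standard error, taken as the absolute log2 change divided by the square root of the test's F statistic. Expression is given as CPM (counts scaled to a common library size, with TMM factors), as mean ± SD with n = 2 in every group. Where a group had 0 counts, the fold is a lower bound against 3 counts over the group. Where a group had 1 to 3 counts, the ratio is given with its exact 95% interval. Such intervals cover counting error only, since reads copied by PCR are not independent molecules.

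Before the data were examined, 29 gene lists with 568 genes were fixed. They cover hormones (auxin response, auxin synthesis and transport, ABA and dehydration, salicylic acid and immunity, jasmonate, ethylene, cytokinin, gibberellin, brassinosteroid), melatonin and tryptophan synthesis, cold, heat shock, iron deficiency, antioxidant enzymes and detoxification. They also cover photosynthesis, chlorophyll synthesis, senescence, energy deprivation, expansins and xyloglucan transferases, the cell cycle, flavonoids, glucosinolates and the circadian clock. Markers of roots, shoot apices, guard cells and seeds stand for tissues or cells that a leaf sample could also hold. Of the 568 genes, 567 are in the table (AOP2 was not found in it) and 472 were tested. One entry, written as GR2, was assigned by the fixed rule for names to AT1G17650 (GLYR2), which differs from the identifier first listed for it. Lists were tested with camera in limma 3.58.1 (two-sided, preset correlation between genes of 0.01), adjusted over the 29 lists. An estimated correlation and fry, whose p tests whether the genes of a list move on balance one way, were alternatives. With an estimated correlation camera has only the 3 residual degrees of freedom of the fit, so few lists can pass. A list not called that way is not thereby shown to be unchanged.

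The genes to be named were set by a rule fixed together with the lists. In each comparison with the control, the rule takes the 6 largest rises and 6 largest falls (4 and 4 between the doses) among genes past the threshold, with a mean CPM of at least 2 and both libraries of a group above both of the other. It adds up to 4 members with the smallest adjusted p of each called list, the member with the smallest p of each other list, and a set of fixed genes, among them IAA19, GH3.3, YUC8, LHCB1.1, RBCS1A, PR1, RD29A and CYCB1;1. Genes outside this rule are said to have been chosen after their values were seen.

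Alternatives planned beforehand were RLE scaling, no filter beyond genes with 0 counts in all libraries, a mean CPM of at least 2, DESeq2 1.42.0, limma-voom, the replicate number as a block, only the 2 groups compared, an added fold of at least 2, library sizes without organelle genes, and leaving out each library in turn. With 1 library left in a group, that library is assumed to vary like the other groups. Fewer libraries also weaken the test, so a call that ends there need not mean that the log2 change moved. The overlap between the doses was set beside 20 simulations of unchanged groups. In these all 6 libraries, controls included, were drawn anew from the mean of the controls, and both doses shared the simulated controls.

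The procedure was tested on simulated counts with known changes in 3 sizes. For 100 µM against control it recovered 43.3% of genes changed 1.5-fold, 80.6% of those changed 2-fold and 97.0% of those changed 4-fold. The shares were 49.3%, 79.1% and 92.4% for 1000 µM against control, and 59.7%, 80.6% and 98.5% between the doses. Unchanged genes made up 5.1%, 6.8% and 10.0% of the calls, above the nominal level in each comparison. Camera called 1 of 29 unchanged lists for 100 µM against control and 0 in each of the other comparisons. The simulated genes were drawn independently and each with the same spread in all groups. The simulation therefore does not show how camera behaves with correlated genes, nor what a wider spread in a single group does to the recovery. Figures were drawn with Python 3.11.15.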

Results

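Gene expression was measured by RNA sequencing in wild-type Arabidopsis thaliana plants that were 7 days old and had spent 12 h with 0, 100 or 1000 µM melatonin, an indoleamine derived from tryptophan. The series title speaks of an adverse effect of melatonin on root growth, whereas the labels name rosette leaves as the tissue. Each of the 3 groups had 2 libraries. The controls held 6784239 and 7333967 counts, the 100 µM libraries 6641570 and 6410046, and the 1000 µM libraries 7651170 and 7723602. Nothing in the labels says that the libraries of a group came from separate plants, so the p-values measure the spread between these libraries, which may be technical.

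The libraries separated by dose on the first principal component, which held 62.3% of the variance, with scores of -36.8 and -36.6 for the controls, -10.2 and -8.35 at 100 µM, and 53.7 and 38.3 at 1000 µM. The 1000 µM libraries differed more from each other than the other pairs did: chi-square per degree of freedom between the libraries of a group was 1.92 in the controls, 1.81 at 100 µM and 5.43 at 1000 µM. Chloroplast genes took 1.01% and 1.15% of the counts in the controls, 1.3% and 1.43% at 100 µM, and 1.36% and 1.06% at 1000 µM. Mitochondrial genes took 0.0454% and 0.0489%, 0.0681% and 0.0833%, and 0.106% and 0.0704% in the same order. Of 23 genes listed as root markers, 15 had more than 3 counts in each of the 6 libraries, and PYK10 (AT3G09260), a beta-glucosidase of roots and hypocotyls, stood at 3246 ± 97.1 CPM in the controls (SD, n = 2).

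The comparison of 100 µM with the control asked what the lower dose did to expression in these libraries. Camera put up the lists of immunity (4 of 25 genes rose), iron deficiency (6 of 16) and detoxification (7 of 33), and put down those of wall loosening (6 of 21 genes fell) and heat shock (5 of 11), but called 0 lists with an estimated correlation (smallest adjusted p = 0.167). PR5 (AT1G75040), a pathogenesis-related thaumatin-like protein, rose from 7.0 ± 1.2 to 50.5 ± 1.5 CPM (SD, n = 2), a log2 change of 2.85 ± 0.16 (adjusted p = 2.07e-08). XTH33 (AT1G10550), a xyloglucan endotransglucosylase/hydrolase of the cell wall, fell from 69.6 ± 0.4 to 30.2 ± 3.1 CPM (log2 change -1.2 ± 0.11, adjusted p = 7.75e-06). Of 18380 genes tested, 610 changed, 329 rising and 281 falling, and 131 changed at least 2-fold, 85 up and 46 down. The count was 334 with DESeq2, 1091 without a filter, 1697 when only these 2 groups were fitted, and 1749 or 1757 without 1000 µM replicate 1 or 2. It was 181 or 191 without control replicate 1 or 2 and 117 or 101 without 100 µM replicate 1 or 2.

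**Figure D1:**
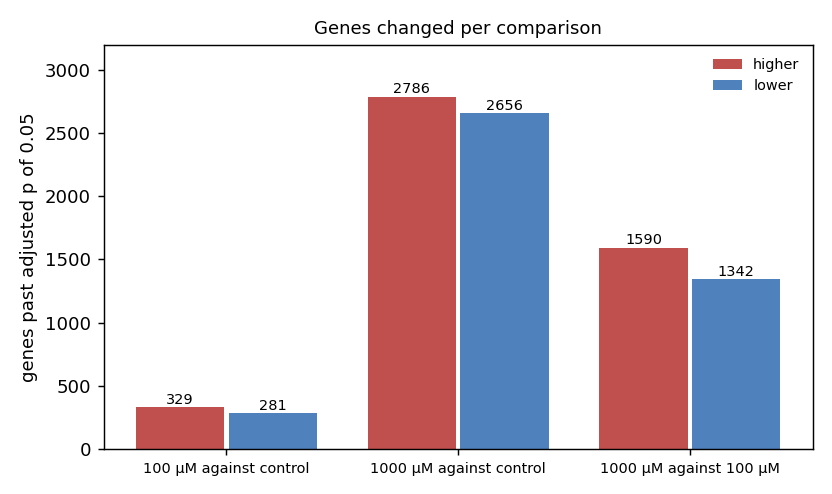
Bars show the number of genes with an adjusted p under 0.05 in each comparison, separately for genes that rose and genes that fell. Against the control, 329 rose and 281 fell at 100 µM, and 2786 rose and 2656 fell at 1000 µM.

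The largest rises at 100 µM included ELIP1 (AT3G22840) and ELIP2 (AT4G14690), which encode light-stress proteins of the thylakoid. ELIP1 rose from 0.5 ± 0.3 to 6.6 ± 0.3 CPM (SD, n = 2; log2 change 3.70 ± 0.39, adjusted p = 2.30e-05), and ELIP2 had a log2 change of 3.1 ± 0.48 (adjusted p = 0.00109). Without control replicate 2 the log2 changes of ELIP1 and ELIP2 were 4.42 and 4.17. The defensin-like gene AT3G59930 rose from 5.0 ± 2.4 to 51.2 ± 6.2 CPM (log2 change 3.33 ± 0.20, adjusted p = 2.07e-08, and 3.93 on the log2 scale without control replicate 2). AT3G13310, a DnaJ-domain protein, rose from 50.2 ± 4.5 to 405 ± 7.2 CPM (log2 change 3.01 ± 0.13, adjusted p = 4.93e-10), and the RNA gene AT1G15405 from 2.3 ± 0.1 to 22.6 ± 9.6 CPM (log2 change 3.31 ± 0.33). GSTU3 (AT2G29470) had so few control counts that its ratio was 9.18, with a counting interval of 2.18 to 81.9, and its adjusted p of 0.0481 became 0.0614 to 0.503 without any one of the 4 libraries compared.

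The largest falls at 100 µM rested on control replicate 2. They were GH3.1 (AT2G14960) and GH3.2 (AT4G37390), whose products join auxin to amino acids, together with PR-1-LIKE (AT2G19990), AT2G19970 and the lipid-transfer gene AT4G15160. Their log2 changes were -2.96, -2.44, -2.89, -2.71 and -1.94 with adjusted p of 0.0339, 0.0148, 0.0167, 0.0129 and 0.0264, and the SD between the controls was close to the mean, as for GH3.2 at 53.9 ± 55.9 CPM (SD, n = 2). Without control replicate 2 the log2 changes were -0.66, -0.53, -0.82, -0.89 and -0.28, and none of the 5 calls was kept, nor was any kept without either 100 µM library, where adjusted p was 0.2 to 0.327 although the log2 changes stayed between -1.93 and -2.99. HSFA2 (AT2G26150), a heat stress transcription factor, fell from 8.8 ± 1.0 to 2.4 ± 0.5 CPM (log2 change -1.88 ± 0.30, adjusted p = 0.00159), a call that ended without 100 µM replicate 2 (adjusted p = 0.0760).

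Of 21 expansins and xyloglucan transferases tested, which loosen or remodel cell walls, 6 fell and 0 rose at 100 µM, and 11 passed when adjusted over the list alone (median log2 change -0.38, camera adjusted p = 3.64e-14, adjusted p = 0.167 with an estimated correlation). Besides XTH33, XTH15 (AT4G14130) fell from 167 ± 9.5 to 82.3 ± 5.7 CPM (SD, n = 2; adjusted p = 1.13e-05) and XTH16 (AT3G23730) from 236 ± 25.9 to 125 ± 7.0 CPM (adjusted p = 3.66e-05). EXPA8 (AT2G40610) fell by 1.36 on the log2 scale (adjusted p = 0.000777), with an adjusted p of 0.0522 without 100 µM replicate 1. Of 23 auxin response genes, 5 fell and 0 rose, and 7 passed when adjusted over the list alone (median -0.43, adjusted p = 1.74e-06, adjusted p = 0.381 with an estimated correlation). This call ended without control replicate 2 (adjusted p = 0.0656), in which 20 of the 23 genes were higher than in control replicate 1. Next to GH3.1 and GH3.2, GH3.6 (AT5G54510) and IAA3 (AT1G04240), an auxin-signalling repressor, fell by 0.55 and 0.62 on the log2 scale (adjusted p = 0.0219 and 0.0243). Neither of these calls was kept without control replicate 2 or either 100 µM library. Log2 changes there were -0.30 to -0.65 for GH3.6 and -0.51 to -0.73 for IAA3. The call of IAA3 also ended without control replicate 1, with a log2 change of -0.66. The fixed auxin genes IAA19 (AT3G15540), GH3.3 (AT2G23170) and YUC8 (AT4G28720) had log2 changes of -0.43, -0.87 and 0.22, with adjusted p of 0.682, 0.146 and 0.887. Each of the 3 turned direction without control replicate 2 (0.70, 0.13 and -0.32), and without control replicate 1 GH3.3 passed (log2 change -1.44, adjusted p = 9.34e-06), as it did without 1000 µM replicate 1 or 2 (0.0177 and 0.0186).

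Of 33 detoxification genes (glutathione transferases, glycosyltransferases and related genes), 7 rose and 0 fell at 100 µM, and 20 passed when adjusted over the list alone (median 0.53, adjusted p = 1.85e-12, adjusted p = 0.167 with an estimated correlation). CYP81D11 (AT3G28740), a cytochrome P450, rose from 25.1 ± 3.2 to 50.1 ± 5.2 CPM (SD, n = 2; adjusted p = 0.000142), and GSTU7 (AT2G29420) from 29.6 ± 1.5 to 53.2 ± 1.9 CPM (adjusted p = 0.000453). GSTU5 (AT2G29450) and GSTU19 (AT1G78380) had log2 changes of 0.58 and 0.61 (adjusted p = 0.00181 and 0.00700). The call of GSTU5 ended without control replicate 1 or either 100 µM library, with log2 changes of 0.53 to 0.58. That of GSTU19 ended without any of the 4 libraries compared, with log2 changes of 0.57 to 0.64. Of 16 iron deficiency genes, 6 rose and 0 fell, and 6 passed when adjusted over the list alone (median 0.22, adjusted p = 1.11e-07, adjusted p = 0.167 with an estimated correlation). BHLH101 (AT5G04150), a transcription factor of the iron deficiency response, rose from 16.4 ± 0.7 to 37.7 ± 3.8 CPM (adjusted p = 8.83e-05). IMA1 (AT1G47400) and IMA2 (AT1G47395), similar genes for iron-sensing peptides whose reads could be shared, had log2 changes of 1.11 and 0.82, and BHLH39 (AT3G56980) of 0.65 (adjusted p = 0.00101, 0.0108 and 0.00700). Without 100 µM replicate 1 their adjusted p was 0.0525, 0.311 and 0.112. The calls of IMA2 and BHLH39 also ended without control replicate 1 (0.164) and control replicate 2 (0.119), respectively, and BHLH39 without 100 µM replicate 2 (0.0970).

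Of 25 salicylic acid and immunity genes, 4 rose and 0 fell at 100 µM, and 5 passed when adjusted over the list alone (median 0.11, adjusted p = 0.00012, adjusted p = 0.317 with an estimated correlation). Beside PR5 these were ICS1 (AT1G74710), an enzyme of salicylic acid synthesis, PBS3 (AT5G13320), also of that pathway, and the receptor-like kinase gene FRK1 (AT2G19190), with log2 changes of 0.88, 1.96 and 0.98 (adjusted p = 0.0119, 0.0135 and 0.0252). Without control replicate 1 or 100 µM replicate 2 their adjusted p was 0.0723 to 0.394. Calls of PBS3 and FRK1 also ended without control replicate 2 (0.103 and 0.114), and those of ICS1 and PBS3 without 100 µM replicate 1 (0.0824 and 0.105). PR1 (AT2G14610) had 0 counts in all 6 libraries and was not tested. Of 10 senescence genes, 2 rose and 0 fell, and 2 passed when adjusted over the list alone (median 0.32, adjusted p = 0.00165, adjusted p = 0.214 with an estimated correlation). They were NYC1 (AT4G13250), a chlorophyll b reductase, and the transcription factor gene ORE1 (AT5G39610), with log2 changes of 0.57 and 0.55 (adjusted p = 0.00192 and 0.0145). Both calls ended without control replicate 2 or either 100 µM library. Log2 changes there were 0.49 to 0.60 for NYC1 and 0.47 to 0.62 for ORE1. The call of ORE1 also ended without control replicate 1, with a log2 change of 0.61.

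Of 11 heat shock genes tested, 5 fell and 0 rose at 100 µM, and 5 passed when adjusted over the list alone (median -0.60, adjusted p = 1.60e-06, adjusted p = 0.214 with an estimated correlation). HSP101 (AT1G74310), a chaperone that takes protein aggregates apart, fell from 37.1 ± 0.7 to 17.7 ± 2.2 CPM (SD, n = 2; adjusted p = 0.000226). MBF1C (AT3G24500) and HSP90.1 (AT5G52640) had log2 changes of -0.85 and -0.75 (adjusted p = 0.00733 and 0.0152), and neither call was kept without control replicate 2 (0.0779 and 0.0566), 100 µM replicate 1 (0.127 and 0.132) or 100 µM replicate 2 (0.0869 and 0.271), nor that of HSP90.1 without control replicate 1 (0.126). Of 12 energy deprivation genes, 1 fell and 0 rose, and 3 passed when adjusted over the list alone (median -0.13, adjusted p = 0.01, adjusted p = 0.254 with an estimated correlation, and 0.0773 without 100 µM replicate 1). This was ASN1 (AT3G47340), an asparagine synthetase, which fell from 791 ± 13.9 to 469 ± 32.0 CPM (adjusted p = 0.0001). Of 41 photosynthesis genes, 1 fell and 0 rose, and 3 passed when adjusted over the list alone (median -0.10, adjusted p = 0.00681, adjusted p = 0.686 with an estimated correlation, and 0.0656 without control replicate 2). LHCB3 (AT5G54270), a light-harvesting protein, fell by 0.43 on the log2 scale (adjusted p = 0.0175). The call ended without any of the 4 libraries compared, with log2 changes of -0.41 to -0.46. LHCB1.1 (AT1G29920) and RBCS1A (AT1G67090) had log2 changes of -0.18 and -0.05 (adjusted p = 0.710 and 0.882). Among genes encoded in the chloroplast, 27 of 88 tested rose and 0 fell.

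The other 20 lists did not pass at 100 µM. Adjusted p was 0.953 for ABA and dehydration, 0.0643 for antioxidant enzymes, 0.100 for auxin synthesis and transport, 0.397 for brassinosteroid, 0.138 for the cell cycle, 0.953 for chlorophyll synthesis, 0.185 for the clock, 0.305 for cold, 0.803 for cytokinin and 0.487 for ethylene. It was 0.220 for flavonoids and for gibberellin, 0.953 for glucosinolates, 0.803 for guard cells, 0.803 for jasmonate and for melatonin synthesis, 0.213 for root markers, 0.368 for seed storage, 0.803 for shoot apex markers and 0.784 for tryptophan synthesis. Among 17 root markers tested, TIP2;3 (AT5G47450) had the smallest adjusted p, 0.295. For ABA, gibberellin, glucosinolates and jasmonate the median, the mean and the test differed in sign. Single genes of these lists changed. RD26 (AT4G27410), a NAC transcription factor of dehydration, rose from 18.7 ± 3.6 to 39.1 ± 0.8 CPM (SD, n = 2; adjusted p = 0.000141), and GASA6 (AT1G74670), a gibberellin-regulated gene, fell from 84.8 ± 2.1 to 31.5 ± 6.4 CPM (adjusted p = 0.000139). PAL2 (AT3G53260), ELF4 (AT2G40080), FSD3 (AT5G23310), ACO4 (AT1G05010), PIN7 (AT1G23080) and TSO2 (AT3G27060) had log2 changes of -0.52, 0.62, 0.56, -0.40, -0.46 and 0.67 (adjusted p = 0.00683, 0.0140, 0.0387, 0.0293, 0.0153 and 0.00135). The calls of PAL2, ELF4, FSD3 and ACO4 ended without any of the 4 libraries compared. Their log2 changes there were -0.51 to -0.53, 0.61 to 0.62, 0.51 to 0.61 and -0.32 to -0.50. The call of PIN7 ended without control replicate 2 or either 100 µM library, with log2 changes of -0.34 to -0.46. That of TSO2 ended without control replicate 1 or 100 µM replicate 2, with log2 changes of 0.60 and 0.64. PDF1.2 (AT5G44420) had a ratio of 12.4 (3.07 to 109) from few control counts, and its adjusted p of 0.0166 became 0.108 to 0.239 without any of these libraries. The members with the smallest p of the remaining lists did not pass: BAS1 (AT2G26710) with an adjusted p of 0.0612, ZAT10 (AT1G27730; 0.0641), MAM3 (AT5G23020; 0.0943), PAT1 (AT5G17990; 0.141), COMT1 (AT5G54160; 0.153), ARR6 (AT5G62920; 0.268), STM (AT1G62360; 0.338), CHLD (AT1G08520; 0.363), CRA1 (AT5G44120; 0.502) and FAMA (AT3G24140; 0.614). The fixed genes RD29A (AT5G52310) and CYCB1;1 (AT4G37490) had adjusted p of 0.867 and 0.943. With only the control and 100 µM libraries fitted, 6 of 62 named-gene results at 100 µM gained a call and 0 lost it.

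The comparison of 1000 µM with the control asked the same of the higher dose. Of the lists that camera called, 28 of 33 detoxification genes and 15 of 25 immunity genes rose, while 28 of 41 photosynthesis genes, 8 of 11 chlorophyll synthesis genes and 14 of 21 wall-loosening genes fell, with 1 immunity gene falling and 4 wall-loosening genes rising. With an estimated correlation camera called 0 lists (smallest adjusted p = 0.0677). GSTU7 rose from 29.6 ± 1.5 to 209.8 ± 22.9 CPM (SD, n = 2; log2 change 2.82 ± 0.11, adjusted p = 9.79e-12). PAL1 (AT2G37040), phenylalanine ammonia-lyase at the entry to phenylpropanoids, fell from 155 ± 1.6 to 36.1 ± 1.3 CPM (log2 change -2.1 ± 0.1, adjusted p = 7.50e-11). Of the 18380 genes, 5442 changed, 2786 rising and 2656 falling, and 1346 changed at least 2-fold, 717 up and 629 down. When only these 2 groups were fitted, 4570 changed. Without control replicate 1 or 2 the count was 3360 or 3318, and DESeq2 gave 3188.

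Among the largest rises at 1000 µM, AT1G60750, an oxidoreductase gene, had 0 counts in the controls and 25.4 ± 4.1 CPM at 1000 µM (SD, n = 2), at least 121-fold higher. ABCG40 (AT1G15520), a membrane transporter of the pleiotropic drug resistance type, rose from 1.0 ± 0.4 to 92.2 ± 34.7 CPM (log2 change 6.52 ± 0.34, adjusted p = 2.28e-10). GSTU3 had a ratio of 72.2 (19.7 to 602), and AT2G47950, AT3G59930 and ELIP1 rose by 5.63, 5.56 and 5.48 on the log2 scale, to 14.8 ± 0.8, 239.7 ± 16.0 and 22.8 ± 1.7 CPM, the last 2 by 6.16 and 6.21 without control replicate 2. The largest falls included AT2G28780, with a ratio of 0.0433 (0.0087 to 0.132), and the acyltransferase gene AT4G15390, from 67.4 ± 9.4 to 5.0 ± 0.6 CPM (adjusted p = 2.45e-11). AIR1 (AT4G12550), named for its induction by auxin in root cultures, fell from 46.6 ± 31.3 to 4.6 ± 1.1 CPM (adjusted p = 3.49e-06), a log2 change of -3.35 that was -2.41 without control replicate 2. AT4G25090, which overlaps CHLM, and the defensin-like gene AT4G22230 fell as well, with log2 changes of -3.27 and -3.25, the last being -2.28 without control replicate 1. PR-1-LIKE fell by 3.33 (adjusted p = 0.00092), a call not kept without control replicate 2. Its log2 change was -1.25 without control replicate 2 and -4.13 without control replicate 1.

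**Figure D2:**
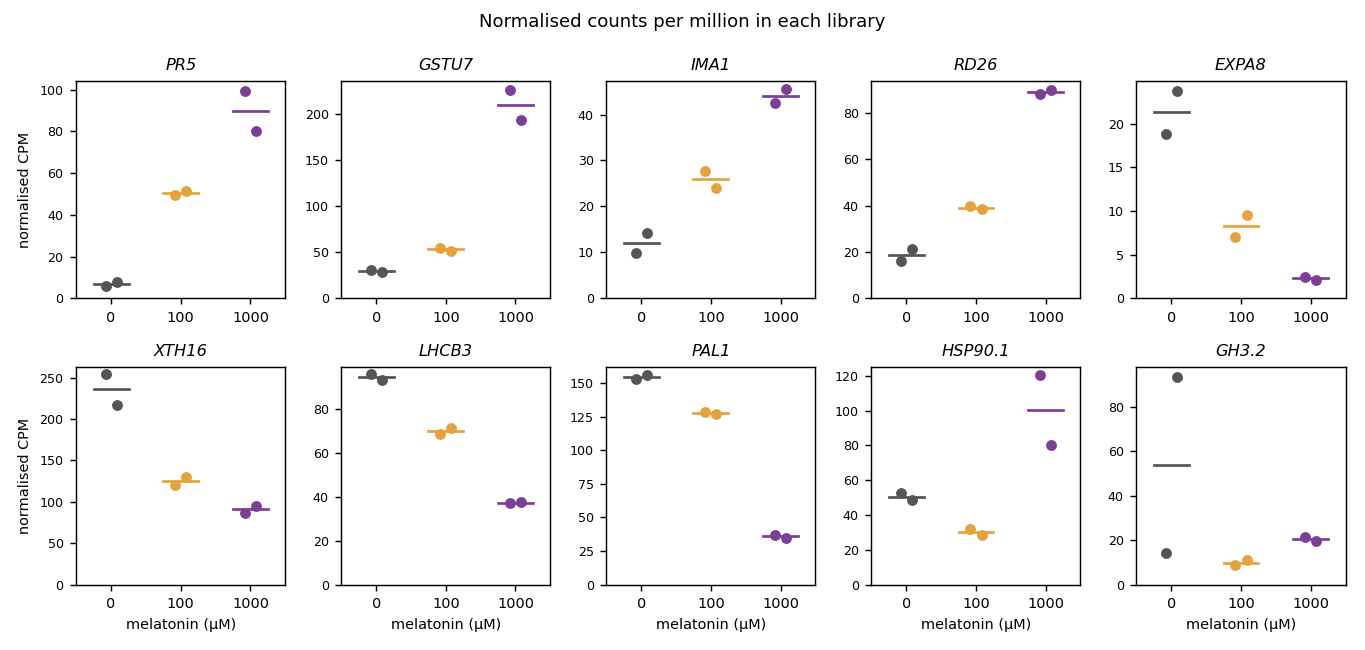
Normalised CPM of 10 genes in each of the 6 libraries, with lines at the group means. PR5 rose from 7.0 CPM in the controls to 50.5 at 100 µM and 89.8 at 1000 µM, while HSP90.1 was lower at 100 µM (30.1) than in the controls (50.6) and higher at 1000 µM (100.4).

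Of the 33 detoxification genes, 28 rose and 0 fell at 1000 µM, and 30 passed when adjusted over the list alone (median 2.1, adjusted p = 2.77e-48, adjusted p = 0.0677 with an estimated correlation). CYP81D11 rose from 25.1 ± 3.2 to 138 ± 7.6 CPM (SD, n = 2; adjusted p = 1.01e-10), GSTU1 (AT2G29490) from 6.3 ± 0.3 to 41.7 ± 2.4 CPM (adjusted p = 7.94e-10), and GSTU19 by 2.26 ± 0.12 on the log2 scale (adjusted p = 2.34e-10). The genes GSTU1 to GSTU7 of this list lie close together and resemble each other, so counts may be shared among them. Of the 25 salicylic acid and immunity genes, 15 rose and 1 fell, and 17 passed when adjusted over the list alone (median 0.43, adjusted p = 6.43e-07, adjusted p = 0.213 with an estimated correlation). PR5 rose to 89.8 ± 13.6 CPM, ICS1 from 11.5 ± 1.6 to 67.1 ± 13.8, FRK1 from 4.6 ± 0.4 to 31.3 ± 1.9 and PBS3 from 1.3 ± 0.2 to 21.3 ± 7.9 CPM. Of 10 senescence genes, 4 rose and 0 fell, and 5 passed when adjusted over the list alone (median 0.35, adjusted p = 0.00505, adjusted p = 0.213 with an estimated correlation). ORE1 rose from 27.8 ± 1.6 to 77.8 ± 0.7 CPM, NYC1 from 143 ± 11.9 to 262 ± 0.8 and SAG21 (AT4G02380) from 249.7 ± 23.1 to 478 ± 16.3 CPM. The pheophytinase gene PPH (AT5G13800) rose by 0.40 on the log2 scale (adjusted p = 0.00835, and 0.144 without control replicate 1).

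Of 16 iron deficiency genes, 8 rose and 1 fell at 1000 µM, and 11 passed when adjusted over the list alone (median 0.42, adjusted p = 0.00143, adjusted p = 0.213 with an estimated correlation). BHLH101 rose from 16.4 ± 0.7 to 58.8 ± 8.9 CPM (SD, n = 2) and IMA1 from 12.0 ± 3.2 to 44.1 ± 2.0 CPM, with log2 changes of 1.32 for IMA2 and 0.92 for BHLH39. Of 8 cold response genes, 4 rose and 0 fell, and 4 passed when adjusted over the list alone (median 0.60, adjusted p = 0.00143, adjusted p = 0.213 with an estimated correlation). The zinc finger genes ZAT12 (AT5G59820) and ZAT10, which respond to many stresses, rose from 12.8 ± 3.6 to 71.2 ± 14.5 and from 40.3 ± 6.9 to 128 ± 29 CPM. COR47 (AT1G20440) rose by 0.44 on the log2 scale (adjusted p = 0.00132) and KIN2 (AT5G15970) by 0.76 (adjusted p = 0.00462, and 0.0887 without control replicate 1).

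Of 41 photosynthesis genes, 28 fell and 0 rose at 1000 µM, and 29 passed when adjusted over the list alone (median -0.48, adjusted p = 2.65e-11, adjusted p = 0.366 with an estimated correlation). LHCB3 fell from 94.6 ± 1.9 to 37.3 ± 0.4 CPM (SD, n = 2; adjusted p = 2.31e-08), RCA (AT2G39730), Rubisco activase, from 7896 ± 471.9 to 3697 ± 0.4 CPM (adjusted p = 4.18e-07), and GAPB (AT1G42970) and LHCB6 (AT1G15820) by 0.93 and 0.79 on the log2 scale. RBCS1A, which has near-identical relatives, fell by 0.49 (adjusted p = 0.00331), a call not kept without control replicate 2 (log2 change -0.42). LHCB1.1 had a log2 change of -0.48 (adjusted p = 0.0613), which was -0.78 without 1000 µM replicate 1. Of 11 chlorophyll synthesis genes, 8 fell and 0 rose, and 9 passed when adjusted over the list alone (median -0.40, adjusted p = 0.0034, adjusted p = 0.213 with an estimated correlation). PORC (AT1G03630) fell from 97.6 ± 4.2 to 63.7 ± 1.5 CPM, CHLM (AT4G25080) and CHLH (AT5G13630) fell by 0.49 and 0.47, and PORB (AT4G27440) by 0.45 (adjusted p = 0.00334, and 0.0628 without control replicate 2). Among genes encoded in the chloroplast, 44 of 88 rose and 10 fell, and among those of the mitochondrion 22 of 49 rose and 0 fell.

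Of 20 flavonoid and phenylpropanoid genes, 9 fell and 1 rose at 1000 µM, and 10 passed when adjusted over the list alone (median -0.79, adjusted p = 7.97e-06, adjusted p = 0.404 with an estimated correlation). The members with the smallest p were those of the general phenylpropanoid steps. PAL2 fell from 166 ± 0.1 to 46.6 ± 6.0 CPM (SD, n = 2), C4H (AT2G30490), cinnamate 4-hydroxylase, from 239 ± 4.1 to 79.4 ± 10.3, and 4CL3 (AT1G65060) fell by 1.28 ± 0.24 on the log2 scale. Of 21 glucosinolate genes, 10 fell and 3 rose, and 14 passed when adjusted over the list alone (median -0.45, adjusted p = 0.00297, adjusted p = 0.404 with an estimated correlation). MAM3 fell from 112 ± 8.0 to 42.3 ± 7.0 CPM, and BASS5 (AT4G12030), BCAT4 (AT3G19710) and CYP83A1 (AT4G13770) fell by 1.59, 1.31 and 1.01 on the log2 scale. These genes act in the synthesis of aliphatic glucosinolates. Of 24 jasmonate genes, 11 fell and 2 rose, and 14 passed when adjusted over the list alone (median -0.52, adjusted p = 0.00143, adjusted p = 0.452 with an estimated correlation). LOX2 (AT3G45140) and AOC2 (AT3G25770), enzymes of jasmonate synthesis, fell from 367 ± 69.4 to 123 ± 16.0 and from 119 ± 12.6 to 41.9 ± 7.7 CPM, and the storage protein gene VSP1 (AT5G24780) fell by 1.76. ORA59 (AT1G06160), which responds to jasmonate and ethylene, rose from 22.5 ± 7.0 to 57.4 ± 19.5 CPM (adjusted p = 6.74e-05).

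Of 21 expansins and xyloglucan transferases, 14 fell and 4 rose at 1000 µM, and 19 passed when adjusted over the list alone (median -0.91, adjusted p = 1.16e-05, adjusted p = 0.213 with an estimated correlation). EXPA8 fell from 21.3 ± 3.5 to 2.3 ± 0.2 CPM (SD, n = 2; adjusted p = 2.96e-08), XTH33 to 17.2 ± 0.5 and XTH16 to 90.9 ± 6.0 CPM, whereas XTH23 (AT4G25810) rose from 145 ± 15.9 to 477 CPM (adjusted p = 6.28e-10). Of 17 root markers, 6 fell and 0 rose, and 8 passed when adjusted over the list alone (median -0.38, adjusted p = 0.0391, adjusted p = 0.366 with an estimated correlation). The list's adjusted p was 0.0577 without control replicate 1 and 0.0563 without 1000 µM replicate 2. PYK10 fell from 3246 ± 97.1 to 2029 ± 31.7 CPM (adjusted p = 4.54e-05) and the aquaporin gene TIP2;3 from 13.2 ± 2.3 to 5.2 ± 0.5 CPM. The root hair genes EXPA7 (AT1G12560) and COBL9 (AT5G49270) fell by 0.92 and 1.04 (adjusted p = 0.0110 and 0.0117), with adjusted p of 0.196 and 0.0870 without control replicate 1, and 0.0644 for COBL9 without 1000 µM replicate 1.

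**Figure D3:**
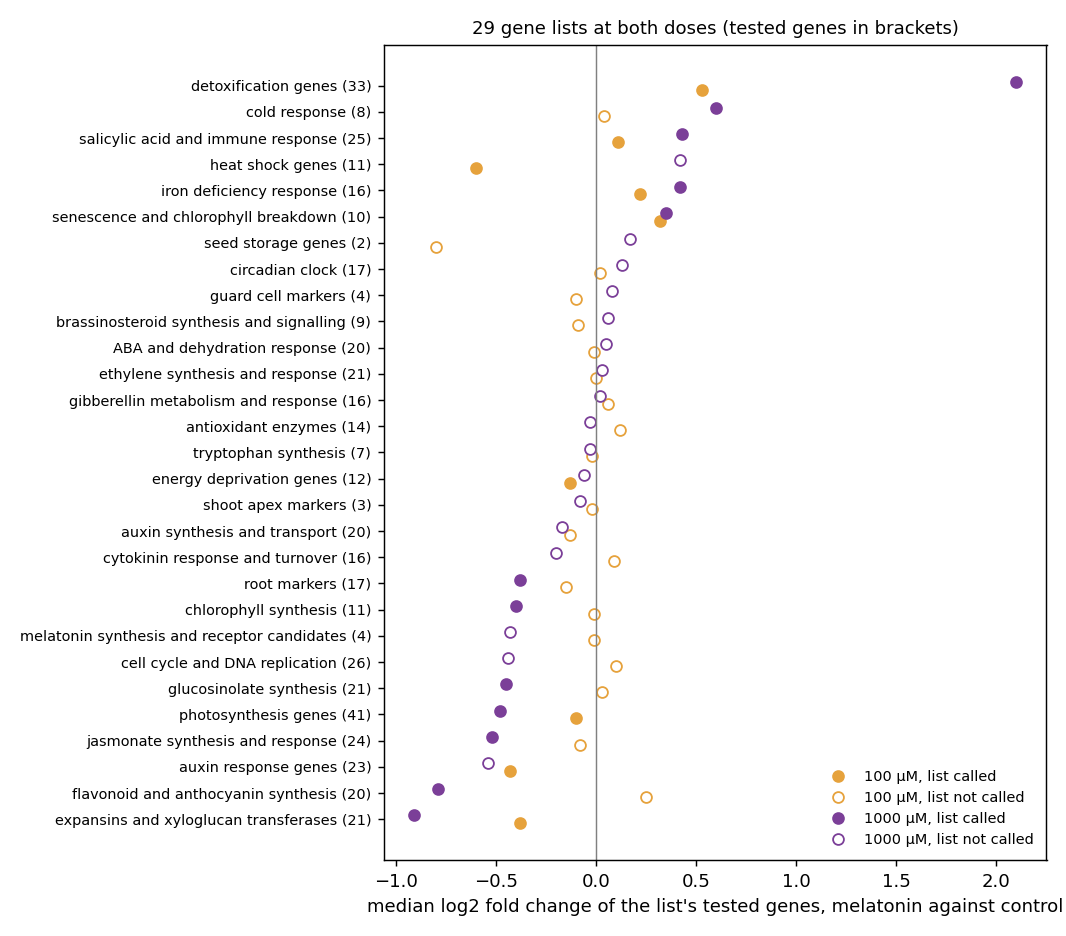
Median log2 change of the tested members of each of the 29 gene lists at 100 and 1000 µM against the control, filled where the list passed camera at an adjusted p under 0.05. Detoxification genes had the highest medians among lists that passed, 0.53 at 100 µM and 2.1 at 1000 µM.

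The other 17 lists did not pass at 1000 µM. Adjusted p was 0.342 for ABA and dehydration, 0.440 for antioxidant enzymes, 0.265 for auxin response, for auxin synthesis and transport, for the cell cycle, for ethylene and for tryptophan synthesis, and 0.872 for brassinosteroid, seed storage and shoot apex markers. It was 0.587 for the clock, 0.856 for cytokinin, 0.495 for energy deprivation, 0.654 for gibberellin, 0.940 for guard cells, 0.488 for heat shock and 0.106 for melatonin synthesis. For antioxidant enzymes, brassinosteroid and gibberellin the median, the mean and the test differed in sign. Of 23 auxin response genes, 8 fell and 2 rose, and 10 passed when adjusted over the list alone. GH3.6 fell by 0.60 (adjusted p = 0.00141, and 0.0834 without control replicate 2), and IAA19, GH3.3 and YUC8 had log2 changes of -0.55, 0.52 and 0.96 (adjusted p = 0.323, 0.159 and 0.111). Which control was kept mattered: without control replicate 1 these were -1.16, -0.05 and 1.77 (adjusted p = 0.0176, 0.839 and 0.0421), and without control replicate 2 they were 0.57, 1.52 and 0.42 (adjusted p = 0.399, 9.31e-07 and 0.598). Of 11 heat shock genes, 5 rose and 2 fell, among the latter HSP101, which fell by 1.1 ± 0.14 on the log2 scale (adjusted p = 1.15e-05). RD26 rose to 89.2 ± 1.4 CPM (SD, n = 2), the glutathione reductase gene GR1 (AT3G24170) from 75.9 ± 2.2 to 155 ± 8.7, ACS7 (AT4G26200), an enzyme of ethylene synthesis, from 9.6 ± 1.1 to 38.2 ± 6.9, and BOA (AT5G59570), a clock gene, from 28.1 ± 2.0 to 65.0 ± 2.2 CPM. TSO2 and CRF6 (AT3G61630) rose by 0.92 and 1.0 on the log2 scale. COMT1, an O-methyltransferase that can act in melatonin synthesis, fell from 244 ± 3.5 to 119 ± 2.0 CPM (adjusted p = 1.74e-07), the auxin influx carrier gene AUX1 (AT2G38120) from 155 ± 1.1 to 86.0 ± 1.8, ASN1 to 356 ± 2.6, and GASA6 to 22.9 ± 9.7 CPM. BAS1 and PAT1 fell by 0.94 and 1.11. KAT1 (AT5G46240), KNAT2 (AT1G70510), CRU3 (AT4G28520), RD29A and CYCB1;1 did not pass (adjusted p = 0.348, 0.531, 0.686, 0.289 and 0.306), although CRU3 passed without control replicate 1 (0.0150).

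The comparison of 1000 with 100 µM asked where the doses differed. Of the lists that camera called, 29 of 33 detoxification genes and 6 of 11 heat shock genes were higher at 1000 µM, while 11 of 20 flavonoid genes, 22 of 41 photosynthesis genes and 6 of 11 chlorophyll synthesis genes were lower, with 1 photosynthesis gene higher. With an estimated correlation camera called 0 lists (smallest adjusted p = 0.0624). GSTU7 rose from 53.2 ± 1.9 to 209.8 ± 22.9 CPM (SD, n = 2; log2 change 1.98 ± 0.11, adjusted p = 3.36e-09) and PAL1 fell from 128 ± 1.3 to 36.1 ± 1.3 CPM (log2 change -1.83 ± 0.10, adjusted p = 3.44e-09). In all, 2932 genes changed, 1590 rising and 1342 falling, and 634 changed at least 2-fold, 397 up and 237 down. The count was 1158 or 1257 without 100 µM replicate 1 or 2, 4442 without 1000 µM replicate 2, and 1567 with DESeq2.

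The largest rises between the doses were ABCG40 (log2 change 5.53 ± 0.31), AT1G60750 (5.35 ± 0.32), AT1G53625 (4.42 ± 0.35) and AT1G56060 (4.03 ± 0.50), with adjusted p of 3.44e-09, 1.45e-08, 1.23e-07 and 2.10e-05. The log2 change was 6.25 for ABCG40 without 100 µM replicate 2 and 5.38 for AT1G53625 without 100 µM replicate 1. The largest falls were the receptor-like protein gene RLP21 (AT2G25470), from 9.2 ± 0.3 to 0.7 CPM (SD, n = 2; adjusted p = 1.05e-06), AT2G28780 with a ratio of 0.0965 (0.0187 to 0.314), LURP1 (AT2G14560) at -2.75 ± 0.46 and SKOR (AT3G02850), a potassium channel of the root stele, at -2.64 ± 0.37. The adjusted p of AT2G28780, 0.00404, became 0.0798 without 100 µM replicate 2.

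Of 33 detoxification genes, 29 rose and 0 fell between the doses, and 29 passed when adjusted over the list alone (median 1.52, adjusted p = 2.14e-53, adjusted p = 0.0624 with an estimated correlation). GSTU19, UGT73B4 (AT2G15490) and CYP81D11 rose by 1.65, 2.29 and 1.46 on the log2 scale. Of 25 salicylic acid and immunity genes, 10 rose and 1 fell, and 14 passed when adjusted over the list alone (median 0.34, adjusted p = 1.61e-05, adjusted p = 0.231 with an estimated correlation). ICS1, FRK1, PBS3 and CBP60G (AT5G26920), a regulator of salicylic acid synthesis, rose by 1.66, 1.76, 2.01 and 1.23. Of 8 cold genes, 4 rose and 0 fell, and 5 passed when adjusted over the list alone (median 0.68, adjusted p = 0.000231, adjusted p = 0.226 with an estimated correlation). ZAT12 and ZAT10 rose by 1.98 and 1.14, and COR47 and KIN2 by 0.42 and 0.73, with adjusted p of 0.0869 and 0.161 for the latter pair without 100 µM replicate 2, and 0.0670 for COR47 without 100 µM replicate 1. Of 11 heat shock genes, 6 rose and 0 fell, and 6 passed when adjusted over the list alone (median 0.61, adjusted p = 1.93e-05, adjusted p = 0.226 with an estimated correlation). HSP90.1 rose from 30.1 ± 2.4 to 100.4 ± 28.1 CPM (SD, n = 2) and HSP70 (AT3G12580) from 89.1 ± 13.9 to 240.3 ± 77.6 CPM, while MBF1C and HSFA7A (AT3G51910) rose by 1.04 and 0.61, the last with an adjusted p of 0.0593 without 100 µM replicate 1. Of 21 ethylene genes, 5 rose and 0 fell, and 7 passed when adjusted over the list alone (median 0.18, adjusted p = 0.0297, adjusted p = 0.402 with an estimated correlation). The list did not pass without 100 µM replicate 1 (0.0725) or 1000 µM replicate 1 (0.0940). ACS7, ACS8 (AT4G37770), ERF5 (AT5G47230) and ERF2 (AT5G47220) rose by 1.32, 1.16, 0.75 and 0.45. The call of ERF5 ended without 100 µM replicate 2 (0.0684), and that of ERF2 without either 100 µM library or 1000 µM replicate 1 (0.107 to 0.285).

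Of 20 flavonoid and phenylpropanoid genes, 11 fell and 0 rose between the doses, and 13 passed when adjusted over the list alone (median -1.11, adjusted p = 2.01e-13, adjusted p = 0.231 with an estimated correlation). PAL2, C4H and CHI (AT3G55120), chalcone isomerase, had log2 changes of -1.32, -1.2 and -1.1, the last with an adjusted p of 0.0633 without 100 µM replicate 1. Of 41 photosynthesis genes, 22 fell and 1 rose, and 31 passed when adjusted over the list alone (median -0.39, adjusted p = 4.40e-13, adjusted p = 0.281 with an estimated correlation). RCA fell from 6748 ± 93.0 to 3697 ± 0.4 CPM (SD, n = 2), and LHCB3, GAPB and LHCB6 by 0.91, 0.79 and 0.64 on the log2 scale. Of 11 chlorophyll genes, 6 fell and 0 rose, and 9 passed when adjusted over the list alone (median -0.34, adjusted p = 4.63e-05, adjusted p = 0.226 with an estimated correlation). PORC fell by 0.77, and CHLI1 (AT4G18480), CHLH and PORB by 0.46, 0.45 and 0.43, the last 3 with adjusted p of 0.0526 without 100 µM replicate 2, 0.0791 without 100 µM replicate 1, and 0.116 and 0.114 without 100 µM replicate 1 and 2, respectively. Of 21 glucosinolate genes, 9 fell and 1 rose, and 11 passed when adjusted over the list alone (median -0.45, adjusted p = 3.58e-05, adjusted p = 0.281 with an estimated correlation). MAM3, BCAT4, BASS5 and MAM1 (AT5G23010) fell by 1.04, 1.23, 1.32 and 0.71, the last with an adjusted p of 0.113 without 100 µM replicate 1. Of 24 jasmonate genes, 10 fell and 1 rose, and 13 passed when adjusted over the list alone (median -0.39, adjusted p = 2.96e-05, adjusted p = 0.330 with an estimated correlation). AOC2, LOX2, JAZ9 (AT1G70700) and VSP1 fell by 1.17, 1.19, 0.66 and 1.58.

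Of 26 cell cycle genes, 3 fell and 0 rose between the doses, and 3 passed when adjusted over the list alone (median -0.54, adjusted p = 0.00475, adjusted p = 0.226 with an estimated correlation, and 0.0545 without 1000 µM replicate 1). CYCD3;1 (AT4G34160), a D-type cyclin, KNOLLE (AT1G08560), a syntaxin of cell plates, and CDKB2;1 (AT1G76540) fell by 0.77, 0.66 and 0.73 (adjusted p = 0.00513, 0.0133 and 0.0170). Their adjusted p was 0.0679 for CYCD3;1 without 100 µM replicate 2, 0.232 for KNOLLE without 100 µM replicate 1, and 0.0898 to 0.135 for CDKB2;1 without either 100 µM library or 1000 µM replicate 1. Of 4 melatonin synthesis and receptor candidates, 2 fell and 0 rose, and 2 passed when adjusted over the list alone (median -0.42, adjusted p = 0.0402, adjusted p = 0.486 with an estimated correlation). COMT1 fell from 204 ± 14.7 to 119 ± 2.0 CPM (SD, n = 2) and ASMT (AT4G35160) by 0.68, with an adjusted p of 0.0506 and 0.267 for ASMT without 100 µM replicate 1 and 2. The list did not pass without 100 µM replicate 2 (0.170) or 1000 µM replicate 2 (0.0891).

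The other 17 lists did not pass between the doses. Adjusted p was 0.209 for ABA and dehydration, 0.932 for antioxidant enzymes, 0.223 for auxin response and for tryptophan synthesis, 0.752 for auxin synthesis and transport, 0.774 for brassinosteroid, 0.931 for the clock and for gibberellin, and 0.624 for cytokinin and for energy deprivation. It was 0.368 for expansins and xyloglucan transferases, 0.830 for guard cells, 0.399 for iron deficiency, 0.0674 for root markers, 0.395 for seed storage, 0.127 for senescence and 0.974 for shoot apex markers. For auxin synthesis, brassinosteroid, the clock and gibberellin the median, the mean and the test differed in sign. XTH23 rose by 1.56 on the log2 scale, RD26 by 1.19, BGLU30 (AT3G60140) by 1.32, GA3OX1 (AT1G15550), an enzyme of gibberellin synthesis, by 1.13, ORE1 by 0.94, CRF6 by 0.92, IMA1 by 0.77, ABCB4 (AT2G47000), an auxin transporter gene, by 0.73, BOA by 0.72, GR1 by 0.66 and IAA7 (AT3G23050) by 0.53. BR6OX2 (AT3G30180) rose by 0.58 (adjusted p = 0.0200), a call that ended without either 100 µM library or 1000 µM replicate 2 (0.0672 to 0.208). PAT1 fell by 0.77 and PYK10 by 0.61. FAMA, STM and CRU3 did not pass (adjusted p = 0.371, 0.272 and 0.203), although this depended on the libraries for CRU3. Its log2 change of 1.01 was 1.34 without 1000 µM replicate 2.

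Both doses moved most of the genes called at 100 µM the same way. Of the 610 genes, 565 (92.6%) were also called at 1000 µM in the same direction, 316 up and 249 down. Independent lists of these sizes would share 90.5 genes, 49.9 up and 40.6 down. In 20 simulations of unchanged groups, with simulated controls shared by both doses, the mean was 0.05 and the highest value 1. With no gene changed few can be called at either dose, so a simulated overlap near 0 was built in. The simulated value leaves out real effects and the other leaves out the shared controls, which were not split because each part would hold 1 library, so part of the excess may come from those controls. Across genes, which are not independent replicates, the log2 changes at the doses correlated at 0.69 against 0.50 in the simulations, and their covariance was 0.164 against 0.028, a difference of 0.136. The overlap was 171 or 181 genes without control replicate 1 or 2, 113 or 99 without 100 µM replicate 1 or 2, 1270 or 1477 without 1000 µM replicate 1 or 2, 953 without a filter and 313 with DESeq2. Between the doses, 298 of the 610 genes changed further in the same direction and 22 in the opposite one. Against the control at 1000 µM, 40 of the 610 were not called, and 5, chosen after their values were seen, were called in the opposite direction: HSP90.1 (log2 changes -0.75 and 0.99), HSP70 (-0.62 and 0.81), AT2G15880 (-0.48 and 0.66), the stress regulator gene DREB2A (AT5G05410; -0.87 and 0.74) and AT5G02760 (-0.44 and 0.34).

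**Figure D4:**
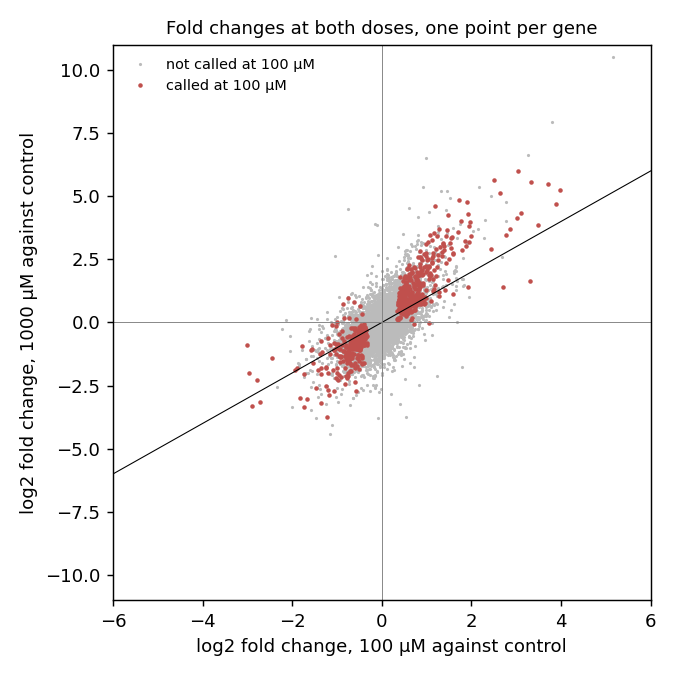
Log2 change of each gene at 100 µM (horizontal axis) and at 1000 µM (vertical axis) against the control, with the line of equal change and the 610 genes called at 100 µM in red. Of these, 565 lie on the same side of 0 and were also called at 1000 µM.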

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

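Leaving out single libraries and testing the difference between the doses were planned, whereas the choice to weigh the auxin pattern and to look at single libraries for the heat shock difference, and the test on root tissue for the auxin pattern, came after the results were seen. Results stand here because their effects against the control pointed in opposite directions at 100 and 1000 µM and the difference between the doses passed edgeR's quasi-likelihood test or, for lists, camera. This held, by the sign of the estimates, for 15 of 133 named genes and 4 of 29 lists. Only HSP90.1 and HSP70, and none of the lists, passed against the control at both doses, and most of the genes did not pass at 100 µM. Some named genes were picked for their change between the doses, so for these passing that test was built in.

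Some heat shock genes were lower than the control at 100 µM and higher at 1000 µM. HSP90.1 differed by 1.73 on the log2 scale between the doses (-0.75 and 0.99 against the control), and HSP70 by 1.43 (-0.62 and 0.81). MBF1C differed by 1.04 (-0.85 and 0.19) but did not pass at 1000 µM (adjusted p = 0.345), and HSP101 fell at both doses. The call of HSP90.1 at 100 µM ended without any of the 4 libraries compared (adjusted p of 0.0566 to 0.271), and that of MBF1C without control replicate 2 or either 100 µM library (0.0779 to 0.127), with log2 changes that stayed between -0.67 and -0.91. The heat shock list had medians of -0.60 and 0.42 and an adjusted p of 1.93e-05 for the difference, which was 0.226 with an estimated correlation, and it did not pass at 1000 µM against the control (adjusted p = 0.488). With the preset correlation the adjusted p of the difference was 1.02e-05 and 8.45e-07 without 1000 µM replicate 1 and 2, and the fall at 100 µM had an adjusted p between 1.59e-07 and 0.000136 without each of the 4 libraries compared, against 0.214 with an estimated correlation and all libraries.

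Auxin and transport genes were among them. GH3.3 differed by 1.39 (-0.87 and 0.52 against the control), but its controls stood at 26.3 and 78.7 CPM, and its changes were -1.44 and -0.05 without control replicate 1, and 0.13 and 1.52 without control replicate 2, so its opposite directions rest on the mean of 2 unlike controls. IAA7 differed by 0.53 (-0.17 and 0.36) and ABCB4 by 0.73 (-0.12 and 0.60). Flavonoid genes had medians of 0.25 and -0.79 (adjusted p of the difference 2.01e-13, and 0.231 with an estimated correlation), and the list did not pass at 100 µM against the control (adjusted p = 0.220). CHI differed by -1.1 (0.15 and -0.95), a call that ended without 100 µM replicate 1 (adjusted p = 0.0633). Cell cycle genes had medians of 0.10 and -0.44 (adjusted p of the difference 0.00475, 0.226 with an estimated correlation and 0.0545 without 1000 µM replicate 1), with 3 of 26 members passing, and the list passed at neither dose against the control (adjusted p = 0.138 and 0.265). KNOLLE differed by -0.66 (0.10 and -0.56), a call that ended without 100 µM replicate 1 (adjusted p = 0.232). The ethylene list had medians of 0.00 and 0.03, its test pointed down at 100 µM and up at 1000 µM, and the difference had an adjusted p of 0.0297, which was 0.402 with an estimated correlation, 0.0725 without 100 µM replicate 1 and 0.0940 without 1000 µM replicate 1. Neither dose passed against the control (adjusted p = 0.487 and 0.265). PORC differed by -0.77 (0.16 and -0.62), CHLI1 by -0.46 (0.16 and -0.30; adjusted p = 0.0526 without 100 µM replicate 2), JAZ9 by -0.66 (0.15 and -0.51) and ARR6, a cytokinin response regulator with few counts, by -1.38 (0.94 and -0.44). AT1G56060 differed by 4.03 (-0.14 and 3.89), RLP21 by -3.63 (0.40 and -3.23) and LURP1 by -2.75 (0.52 and -2.23).

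The fall of auxin response genes at 100 µM was weighed because GH3.1 and GH3.2 were among the largest falls. The list's adjusted p of 1.74e-06, which was 0.381 with an estimated correlation, became 0.0656 without control replicate 2, its median moved from -0.43 to -0.17, and the members that fell went from 5 to 0, while the list passed without each of the other 5 libraries, although 0 members fell without either 100 µM library. This is consistent with a single library, control replicate 2, carrying much of the pattern. The root markers tested pointed away from more root tissue in that library. They had a median log2 ratio of -0.20 over control replicate 1 (95% bootstrap interval -0.45 to 0.08), against 0.36 (0.10 to 0.55) for the auxin genes. However, 6 of the 17 were higher in control replicate 2. The intervals resample genes of a single pair of libraries, which are not independent replicates, and some markers are also expressed outside roots. More root tissue is thus not excluded. A lower auxin response under melatonin stays open, and with 2 controls the data do not say which of them is typical.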

How the results depend on the processing

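All alternatives in this part were planned, and none was chosen after the results were seen. No list or named gene with a call changed direction in any setting, and for the other called genes this was not checked. Over the list results, 881 of 957 stayed as they were, called or not called, 54 lost a call and 22 gained one. Over the named genes 3024 of 3295 stayed as they were, 234 lost a call and 37 gained one. Results never called count among those that stayed, so these shares do not measure how many calls were kept. Camera with an estimated correlation left 54 of 87 list results as they were, yet ended 33 list calls and kept none. The added fold of at least 2 ended 73 named-gene calls, more than any other setting. Leaving out either 100 µM library ended 38 named-gene calls each, leaving out control replicate 1 or 2 ended 21 and 27, and DESeq2 ended 21. RLE scaling (597, 5417 and 2909 genes at 100 µM, at 1000 µM and between the doses), limma-voom (552, 5405 and 2875), a mean CPM of at least 2 (602, 5320 and 2881) and library sizes without organelle genes (605, 5474 and 3022) stayed within 1.5 times the counts reported.

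At 100 µM against the control, 610 genes became 1091 without a filter, 1697 with only the 2 groups, 334 with DESeq2, 131 with a fold of at least 2 as well, and 101 to 1757 with a library left out. At 1000 µM, 5442 became 3188 with DESeq2, 1346 with the fold, and 3318 to 6684 with a library left out. Between the doses, 2932 became 1567, 634 and 1158 to 4442. The overlap of 565 genes became 953 without a filter, 313 with DESeq2 and 99 to 1477 with a library left out. The fold adds a condition, and for the other settings the cause was not tested. The groups share an estimate of the spread, and the 1000 µM libraries differed most from each other. Chi-square per degree of freedom was 5.43 there, against 1.92 in the controls and 1.81 at 100 µM. Fitting only the 2 groups compared, which also changes filter and scaling, moved 610 to 1697 genes and 5442 to 4570. The counts at the doses thus depend on libraries outside the comparison, and the gap between 610 and 5442 was wider than that between 1697 and 4570. Without either 1000 µM library BAS1 and ZAT10, which gained a call at 100 µM, kept log2 changes of -0.52 and 0.53. Their estimates did not move, which goes with a part for the shared spread. How large that part is was not tested apart from filter and scaling. Camera with an estimated correlation called 0, 0 and 0 lists in place of 9, 12 and 12, and fry called 2, 19 and 12. With 3 residual degrees of freedom the estimated correlation left little room to pass. At 1000 µM the detoxification list, with 28 of 33 genes rising, had an unadjusted camera p of 0.00234 in that setting. Of the calls by fry, 1, 12 and 9 were also calls of camera with the preset correlation, in the same direction. With a library left out, camera called 8 to 11, 11 to 12 and 10 to 13.

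With the replicate block, edgeR called 446, 4959 and 2508 genes, 420 in the overlap, and camera 9, 12 and 12 lists, with 4 named-gene calls lost and 2 gained. The numbers do not pair the libraries: deviations from the group means correlated at 0.028, -0.031 and -0.066 between the groups. What depth limits was not tested apart from the number of libraries: in simulated data with 2 libraries per group, 43.3% of genes changed 1.5-fold were recovered at 100 µM.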

Other observations

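The gene families here were chosen after a scan of 231 groups, 44 of them written by hand and some overlapping, and of the tests on root markers and organelle genes only the one on nuclear RNA without poly(A) tails was chosen before its result was seen. At 1000 µM against the control camera called 28 of the 231 groups, and 0 with an estimated correlation (smallest adjusted p = 0.603). Of 49 NAC transcription factor genes, 21 rose and 0 fell (adjusted p = 2.15e-06), among them ATAF1 (AT1G01720) from 43.7 ± 2.0 to 259 ± 44.4 CPM and NAC001 (AT1G01010) from 5.9 ± 0.8 to 41.6 ± 2.2 CPM (SD, n = 2). Of 34 proteasome subunit genes, 23 rose and 0 fell (adjusted p = 8.16e-05), such as PAD1 (AT3G51260), a 20S subunit gene, from 53.9 ± 6.1 to 91.3 ± 6.5 CPM. Of 309 ribosomal protein genes, 64 rose and 6 fell (adjusted p = 0.0209). Their median log2 change was 0.18, close to the 0.15 at 100 µM, and camera did not call them between the doses (adjusted p = 0.967). Of all 18380 genes tested, 29.6% changed at 1000 µM, 2786 rising and 2656 falling. Of 14 multidrug resistance-associated transporter genes, 8 rose and 0 fell (adjusted p = 0.0186), and of 92 UDP-glycosyltransferase genes 28 rose and 15 fell (adjusted p = 0.00244), with UGT73B2 (AT4G34135) going from 34.7 ± 1.5 to 371 ± 4.3 CPM.

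Of 39 pectin lyase-like genes, 16 fell and 0 rose at 1000 µM (adjusted p = 3.80e-06), with PME5 (AT5G47500) going from 43.4 ± 3.4 to 13.3 ± 2.3 CPM (SD, n = 2). With an estimated correlation neither this call nor any other of this paragraph was kept (adjusted p of 0.603 to 0.919). Of 39 arabinogalactan protein genes, 12 fell and 3 rose (adjusted p = 0.0194), and AGP18 (AT4G37450) went from 94.9 ± 6.6 to 33.2 ± 2.6 CPM. Of 25 aquaporin genes, 14 fell and 3 rose (adjusted p = 0.00116), with PIP3 (AT4G35100), a plasma membrane water channel, going from 959 ± 50.4 to 469.8 ± 10.4 CPM. Of 27 serine carboxypeptidase-like genes, 15 fell and 2 rose (adjusted p = 0.00144), among them SCPL13 (AT2G22980) from 52.8 ± 7.6 to 12.2 ± 5.3 CPM. Of 27 kinesin genes, 14 fell and 0 rose (adjusted p = 0.0241). Of 13 genes named root hair specific, 6 fell and 0 rose (adjusted p = 0.0266). Of 55 peroxidase genes, 17 rose and 18 fell (adjusted p = 0.850), PER4 (AT1G14540) going from 2.0 ± 0.1 to 38.4 ± 9.5 CPM.

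Root markers were present in libraries described as leaf. More than 3 counts in each library were found for 15 of 23 of them, led by PYK10 at 3246 CPM in the controls, followed by PHT1;1 with 146 and 171 CPM. This is consistent with some root tissue in the libraries, although SCR and SHR are also expressed in leaves and PYK10 in hypocotyls. At 1000 µM 6 of 17 tested markers fell and 0 rose, but the log2 changes were not alike. They ran from -1.44 to 1.46 around a weighted mean of -0.46. The spread exceeded their errors (chi-square test of heterogeneity over the 17 genes, p = 3.24e-07, Q = 61.2, 16 degrees of freedom). The highest value was that of WOX5, with 5 and 2 counts in the controls. A lower root share would give like falls only in markers expressed in roots alone, so this test cannot decide on it. A lower root share and changes of expression within root cells stay open, and the latter were not tested.

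Chloroplast genes were higher at 100 µM, 27 of 88 rising and 0 falling with a median log2 change of 0.63. Among the most abundant of them, ATCG00020 rose by 1.91 ± 0.21. By contrast, ATCG00480, ATCG00470, ATCG00220 and ATCG01130 did not pass, with log2 changes of -0.13, 0.15, 0.24 and -0.32. The chloroplast genes did not move by one amount: log2 changes ran from -2.04 to 1.94 around a weighted mean of 0.34 (chi-square test of heterogeneity over the 88 genes, p = 1.11e-88, Q = 658.8, 87 degrees of freedom), which argues against one common rise of chloroplast RNA. Of 49 mitochondrial genes 5 rose and 0 fell, with a median of 0.32, and their spread was not tested. Carry-over of RNA without poly(A) tails cannot be told apart from a change in the plastids. The 17 nuclear small RNA genes tested had a median of 0.11, and its 95% bootstrap interval of -0.17 to 0.33 is too wide to decide. Whether poly(A) RNA was selected is not given in the sources used here, so the source of the change stays open.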
